A study of Arabidopsis thaliana with 18 samples.

How the data were processed

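RNA from rosette leaves of Arabidopsis thaliana was measured on 18 single-colour Agilent arrays of design 021169, each holding 43603 probes that are not controls. Plants were the Col-0 wild type (WT) and max2-3, a mutant of the F-box gene MAX2 that is impaired in the response to strigolactones. Per the labels, shoots of 24-day-old plants were detached and left to dry for 0, 2 or 4 h, and 3 independent biological replicates were taken for each of the 6 combinations of genotype and time. The p-values below therefore measure the spread between separate samples of plants, as far as the labels state it, and 3 arrays per group limit the precision.

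The deposited scanner files hold spot intensity values on a linear scale, written by Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 per the file headers. The processed intensity had already had background subtracted and a spatial trend removed by the scanner software, per the file headers. The deposited series table holds log2 values. These matched log2 processed intensity minus each array's 75th percentile, centred per probe near the median of the 18 arrays, which was found from the values, with correlations of 0.979 to 0.997 with scanner values treated the same way. Its column medians ran from -0.093 to 0.08. How the authors made that table is not given in the sources used here, and it was used only as an alternative.

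From there, log2 processed intensity minus each array's 75th percentile was computed, control spots were left out, and spots with an outlier flag were set to missing (153 values among the genes tested). Of the probes, 38413 carry a locus identifier, for 29030 loci, of which 28596 were found in the reference gene table of TAIR10.1, used here for names only. A further 5190 probes carry none and were not analysed here, and 873 probes list another locus beside their own. Where a locus had several probes, the brightest over all arrays stood for it, with the mean of all its probes as an alternative. A gene was tested when its probe was well above background on all 3 arrays of at least 1 group; a flagged spot did not count against it if 2 arrays remained. This left out 8061 loci, of which 5613 were not well above background on any array, and kept 20969, of which 18203 were well above background on all arrays. Where a probe was not well above background on any array of a group, the text gives the other group as "at least N-fold". That bound sets the bright group's mean against, per array, the higher of the probe's own signal and the lowest signal among probes well above background. A difference of responses has such a bound only where each group below background enters it against its sign.

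Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 6 group means over all 18 arrays, which share 1 estimate of the spread per gene). Adjusted p is limma's p after Benjamini-Hochberg adjustment over all genes of a contrast. A gene was called at adjusted p under 0.05 and a change of at least 2-fold. The 9 contrasts were max2-3 against WT at 0, 2 and 4 h, each genotype at 2 and 4 h against its own 0 h, and the difference between genotypes of the 2 h and of the 4 h response. Changes are given on the log2 scale with the standard error (SE) from the fit. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

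There were 29 gene lists, 5 of them markers of cell types or tissues, and of 429 members 419 were kept and 10 were dropped because their name disagreed with the reference. Each list was tested with limma's camera, which compares its members with all other genes, at a preset correlation of 0.01 between genes and with adjustment over the lists within a contrast. The alternatives were a correlation estimated from the data and fry, which asks whether members move one way and compares them with no other genes. Members were counted as higher or lower at adjusted p under 0.05 with no fold minimum, over all genes and again adjusted over the list alone. The 117 genes with a missing value stayed out of list tests. Of the list calls, that of the strigolactone and karrikin list at 0 h is the only one that holds with an estimated correlation. These adjusted p are given beside the lists.

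The genes named were set by a rule: MAX2; the 6 largest rises and 6 largest falls among called genes whose arrays do not overlap between the groups (10% of genes meet that by chance with 3 arrays against 3; for the differences of responses, all called genes); up to 4 members of each list with the largest changes at adjusted p under 0.05; and the 4 genes with a symbol and the lowest adjusted p. Groups, tests, lists, this rule and the alternatives were fixed before the data were examined.

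The fits were tested on simulated data made from the real genes' means and spreads, with 50 genes changed at each fold. For max2-3 against WT at 4 h, on 20852 genes, 36% of genes changed 2-fold, 92% of those changed 3-fold and 94% of those changed 4-fold were called, with 0 calls among 20652 unchanged genes (6 at adjusted p alone, 3.5% of such calls). In the other contrasts 1 to 5 unchanged genes were called, and at adjusted p alone 3.9% to 7.3% of the calls were of unchanged genes.

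Arrays lay on 5 slides. Slide 1 held the 3 WT 0 h arrays and WT 2 h replicate 1, slide 2 the other WT 2 h arrays with WT 4 h replicates 1 and 2, and slide 3 WT 4 h replicate 3 with the 3 max2-3 0 h arrays. Slide 4 held max2-3 2 h alone and slide 5 max2-3 4 h alone, so slide and group cannot be told apart for these 6 arrays. Slide was fitted as a fixed block and as a random block, and WT 2 h was compared with 0 h within slide 1. The other alternatives were normexp background correction on the raw mean and background intensity with quantile normalization, quantile normalization alone, median centring, the series table, no filter and a stricter filter on dim probes, a trended and robust eBayes, array weights, a fit of the compared groups alone, the replicate number as a block, no fold minimum, and leaving out each array in turn.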

Results

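Rosette leaves of WT and max2-3 were measured well watered (0 h) or after 2 or 4 h of drying, with 3 arrays per group. The labels name no group kept undried for 2 or 4 h. Changes from 0 h therefore cannot tell drying apart from detaching the shoot or from the later hour. The scanner's 75th percentile of processed intensity ran from 1848 to 2392 on the 12 arrays of WT and of max2-3 at 0 h. It was lower, from 1105 to 1478, on the 6 arrays of max2-3 at 2 and 4 h. Between 67.7% and 71.4% of spots were well above background on each array, and 0 spots were saturated on any. The median SD between replicates was 0.097 to 0.143 on the log2 scale.

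Over the 20852 genes with a value on every array, the first principal component held 64.3% of the variance and the second 18%.

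**Figure D1:**
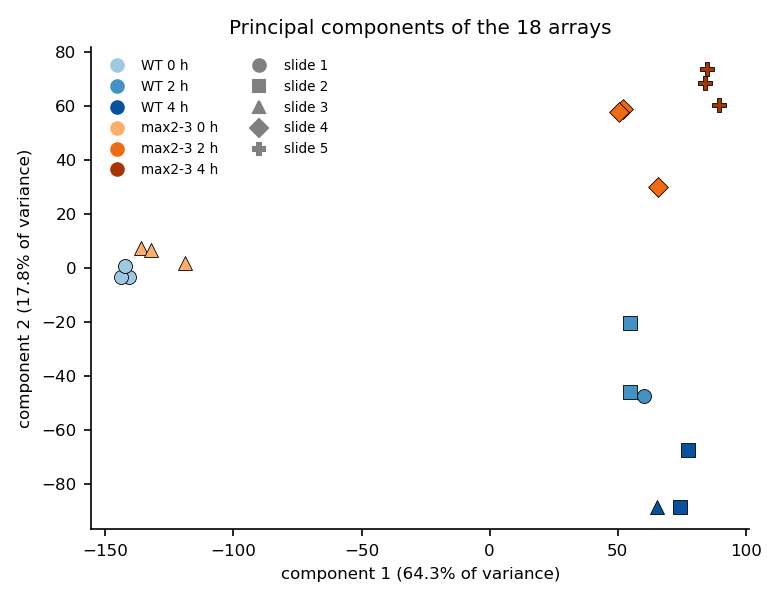
Each point is 1 of 18 arrays, placed by its first and second principal components over genes with a value on every array, with colour for the group and shape for the slide. The first component parts the 0 h arrays from the dehydrated ones, and the second the genotypes among the dehydrated arrays.

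The labels do not say where the max2-3 lesion lies, so the MAX2 probe checks nothing about the genotype. The 1 probe for MAX2 (AT2G42620) matches chromosome 2 from 17765174 to 17765233 in the array file's ath1:Jan2004 build and was well above background on all arrays. Its log2 level was 0.002 ± 0.141 (SD, n = 3) in WT and 0.51 ± 0.121 in max2-3 at 0 h, a difference of 0.51 (SE 0.14, adjusted p = 0.0125). That difference passed the test neither with slide as a block (0.63, adjusted p = 0.288) nor without WT 0 h replicate 1 (0.43, 0.0516) or max2-3 0 h replicate 3 (0.45, 0.0534). At 2 h it was 0.08 (adjusted p = 0.643) and at 4 h 0.05 (adjusted p = 0.736). Within max2-3 the MAX2 signal fell by 0.62 at 2 h (adjusted p = 0.000902) and by 0.49 at 4 h (adjusted p = 0.00439), the latter not passing the test under median centring (-0.24, 0.136). In WT the changes were -0.20 (adjusted p = 0.214) and -0.04 (adjusted p = 0.813), and the differences between the genotypes' responses were -0.43 (adjusted p = 0.0888) and -0.45 (adjusted p = 0.0527).

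The first comparison was of well-watered max2-3 with WT. Transcripts tied to strigolactone and karrikin signalling were lower in max2-3: KUF1, an F-box gene induced by karrikins, by a log2 change of -4.56 (SE 0.14, adjusted p = 1.18e-10, n = 3 per group), AT2G40130 (SMXL8), a target of MAX2-dependent degradation, by -3.99 (SE 0.19, adjusted p = 1.67e-08), and BRC1, a repressor of bud outgrowth, by -4.99 (SE 0.37, well above background on 1 of 3 mutant arrays). AT3G24420 fell by 8.92 (SE 0.34, 1 of 3 mutant arrays above background), and AT1G30250 was at least 250-fold lower. MRD1 was lower by -6.05 (SE 0.24), AT3G60290 by -5.87 (SE 0.18) and KCR2 by -4.00 (SE 0.14). The largest rises were in AT5G35935, at least 89.6-fold, DIR5, at least 35.9-fold, AT2G37870, 5.22 (SE 0.34, 2 of 3 WT arrays above background), ELI3-2, 4.85 (SE 0.66), LEA7, at least 15-fold, and AT5G44440, at least 15.4-fold. In all, 1030 genes were called, 597 higher and 433 lower in max2-3.

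Among 18 measured genes of the strigolactone and karrikin pathway, 12 were lower and 2 higher (12 and 4 adjusted over the list alone). Their median was -1.19 (adjusted p = 1.01e-06, and adjusted p = 0.00528 with an estimated correlation). HB40, a homeobox gene downstream of BRC1, was at least 23.3-fold lower. Of 22 dehydration and ABA response markers, 9 were higher and 1 lower (13 and 1 adjusted over the list alone). The median was 0.63, or 0.52 with genes at their bound (adjusted p = 0.00542, and adjusted p = 0.667 with an estimated correlation). COR15A, a chloroplast protein of cold and drought tolerance, rose by 2.17 (SE 0.21, adjusted p = 1e-05), HIS1-3, a linker histone, by 1.39 (SE 0.24), and KIN2 by 1.22 (SE 0.16). The auxin list had 9 of 15 members higher and 1 lower (10 and 1 adjusted over the list alone). The median was 0.52 (adjusted p = 0.00542, and adjusted p = 0.489 with an estimated correlation). Its members IAA6 and IAA5, early auxin-induced repressors, rose by 2.07 (SE 0.16) and 2.01 (SE 0.24), and IAA29 fell by 2.48 (SE 0.31). Jasmonate genes were higher in 10 of 25 and lower in 0 (11 and 0 adjusted over the list alone), among them AOC2, 1.77 (SE 0.14), and JAZ5, 1.62 (SE 0.20). Their median was 0.36 (adjusted p = 0.000745, and adjusted p = 0.598 with an estimated correlation).

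A further 3 lists passed at 0 h. Salicylate and defence genes were lower in 6 of 16 and higher in 1 (the same counts adjusted over the list alone), led by SARD1, a regulator of salicylate synthesis, at -2.35 (SE 0.34). The median was -0.42 (adjusted p = 0.0322, and adjusted p = 0.802 with an estimated correlation). PR1, on the same list, was higher by 3.88 (SE 1.2, adjusted p = 0.0243), a call lost without WT 0 h replicate 1 (3.58, adjusted p = 0.0721) or replicate 2 (2.5, 0.115) and without max2-3 0 h replicate 2 (3.41, 0.0896) or replicate 3 (3.79, 0.0668). The salicylate call was lost without WT 0 h replicate 1 (mean -0.18, adjusted p = 0.0769) or replicate 3 (0.03, 0.119) and without max2-3 0 h replicate 1 (0.11, 0.22) or replicate 3 (0.03, 0.124), so that 3 of these means lay above 0 where all arrays gave -0.28. The mean was -0.50 without WT 0 h replicate 2, -0.80 without max2-3 0 h replicate 2, -0.64 over genes above background on all arrays alone and -0.18 with array weights. It was also lost under normexp with quantile (adjusted p = 0.0515), median centring (0.0502), the mean of all probes (0.0624), a fit of these groups alone (0.057) and fry (0.149). Low-oxygen genes were higher in 4 of 9 and lower in 0 (4 and 0 adjusted over the list alone), with ADH1 at 1.24 (SE 0.32) and LBD41 at 0.72 (SE 0.16). Their median was 0.72 (adjusted p = 0.0322, and adjusted p = 0.667 with an estimated correlation). That call was lost without WT 0 h replicate 1 (mean 0.78, adjusted p = 0.054) or 2 (0.78, 0.0537) and without max2-3 0 h replicate 2 (0.54, 0.118), and with the mean of all probes (0.0624). Epidermis markers were lower in 3 of 6 (3 adjusted over the list alone), and lost their call without WT 0 h replicate 1 (mean -0.30, adjusted p = 0.0854) or 2 (-0.30, 0.0537) and without max2-3 0 h replicate 2 (-0.29, 0.0787), with the mean of all probes (0.064) and in a fit of these groups alone (0.057). The median was -0.34 (adjusted p = 0.0322, and adjusted p = 0.489 with an estimated correlation).

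The remaining 22 lists were not called at 0 h. ABA-related lists had medians of -0.24 for synthesis (adjusted p = 0.176), 0.03 for breakdown and transport (0.734), -0.29 for receptors (0.126), -0.08 for clade A protein phosphatases 2C (0.783), -0.12 for SnRK2 kinases (0.392) and 0.02 for stress transcription factors (0.652). Within them, CYP707A2 and CYP707A3, which both break down ABA, moved apart, by 2.29 (SE 0.19) and -2.15 (SE 0.24), and the transporter ABCG22 was lower by -2.84 (SE 0.16). Cytokinin metabolism had a median of -0.04 (0.871), with CKX1, a cytokinin oxidase, at -3.29 (SE 0.34), and type-A response regulators -0.11 (0.376). Photosystems stood at 0.03 (0.871), anthocyanin synthesis at 0.001 (0.871) with PAP1 at 1.33 (SE 0.26), senescence at -0.14 (0.126), wax and cutin at 0.04 (0.652), osmolytes at -0.19 (0.652), aquaporins at 0.07 (0.871) and heat shock at -0.23 (0.734). The medians were -0.36 for touch (0.394), -0.36 for the clock (0.0906), 0.007 for antioxidant enzymes (0.652), 0.14 for guard cells (0.871), 0.51 for vascular tissue (0.176), 0.22 for flowers (0.652) and 0.04 for dividing cells (0.933). Median and mean differed in sign for stress factors, ABA breakdown, senescence, wax, antioxidant and flower lists, and the test's direction opposed both for dividing cells.

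The WT arrays of this comparison lay on slide 1 and the max2-3 arrays on slide 3, so no value within a slide can be had. With slide as a block, linked only through WT arrays at 2 and 4 h, 77 genes were called, 30 higher and 47 lower. KUF1 (-4.59, adjusted p = 9.09e-05), AT2G40130 (-4.21, 0.025), BRC1 (-5.84, 0.00162), KCR2 (-3.94, 0.00255), MRD1 (-6.12, 0.00676), AT3G24420 (-8.52, 0.00262), AT3G60290 (-5.60, 0.000748), AT2G37870 (5.28, 0.0161), CKX1 (-4.06, 0.00676), ABCG22 (-2.55, 0.0466) and IAA6 (2.77, 0.0288) passed that test. COR15A (2.59, 0.0531), HIS1-3 (1.68, 0.234), KIN2 (1.29, 0.288), AOC2 (1.63, 0.0838), JAZ5 (1.70, 0.291), IAA5 (1.72, 0.324), SARD1 (-3.22, 0.158), CYP707A2 (1.86, 0.074) and CYP707A3 (-2.11, 0.0823) did not, nor did ELI3-2 (5.06, 0.317), IAA29 (-2.81, 0.14), PAP1 (1.02, 0.479), PR1 (3.74, 0.681), ADH1 (1.85, 0.383) and LBD41 (0.48, 0.732). Of the genes with only a bound at 0 h, for which the block gives no size, AT1G30250 passed (adjusted p = 0.000804) and HB40 (0.0734), DIR5 (0.0649), LEA7 (0.18), AT5G35935 (0.15) and AT5G44440 (0.106) did not. List means with the block were -1.34 for strigolactone genes (adjusted p = 3.38e-07), 0.98 for ABA markers (0.000991), 0.52 for auxin (0.0264) and -0.76 for salicylate (0.0032). Those of jasmonate (0.25, 0.0834), low oxygen (0.84, 0.065) and epidermis (-0.26, 0.304) no longer passed.

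The next comparisons set WT at 2 and 4 h against 0 h. Among single genes, TSPO, a membrane protein of the stress response, was at least 3340-fold higher at 2 h and at least 7150-fold at 4 h, and LEA7, a protective late embryogenesis abundant protein, at least 1730-fold and at least 5590-fold. EDL3, an F-box regulator of ABA signalling, rose by 9.60 (SE 0.19, n = 3 per group) and 9.05, and PUB19 was at least 1180-fold higher at 2 h. UGT76E12 was at least 1830-fold higher at 2 h and at least 1310-fold at 4 h. The expansin gene EXPA8, which loosens cell walls, fell by 7.32 (SE 0.48) at 2 h and fell by 8.66 at 4 h (2 of 3 arrays above background), and XTH25, a wall-modifying enzyme, was at least 191-fold lower at 4 h. Of all genes, 6079 were called at 2 h, 3215 higher and 2864 lower, and 7248 at 4 h, 3494 higher and 3754 lower, the latter balance turning under median centring (3748 and 3493).

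**Figure D2:**
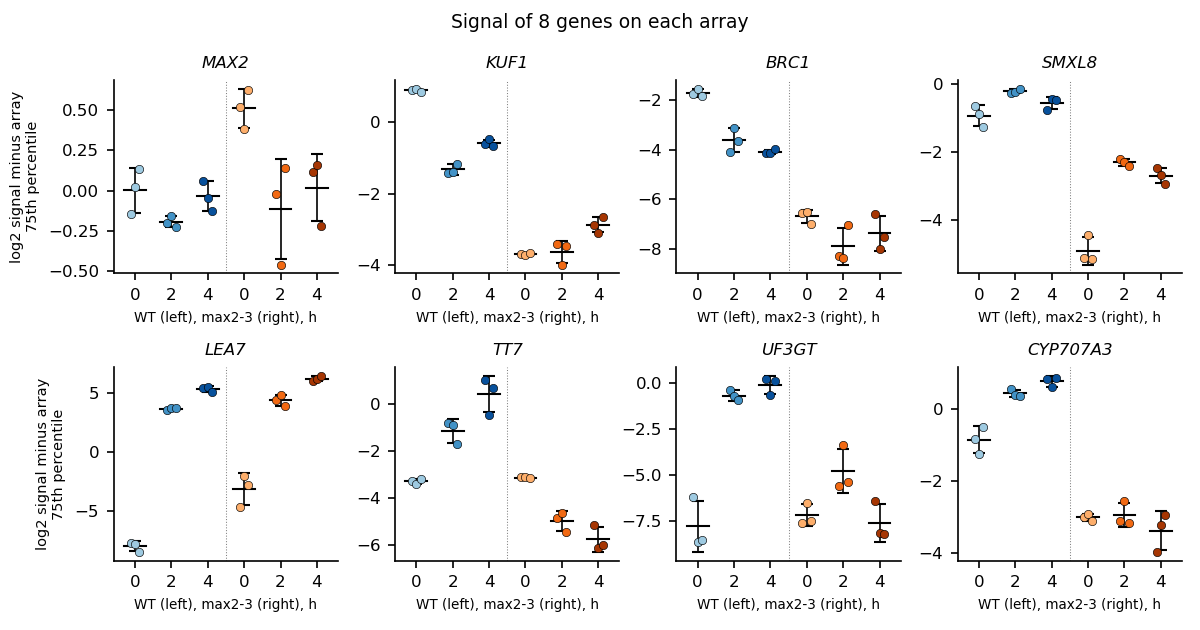
Each panel plots the log2 signal of 1 of 8 genes minus the array's 75th percentile, against hours of dehydration, with WT on the left, max2-3 on the right, a point per array, and the mean and SD of 3 arrays. KUF1 is lower in max2-3 by a log2 change of -4.56 at 0 h, and the MAX2 panel spans a far smaller range than the others.

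In WT at 2 h, all 22 dehydration and ABA markers were higher (22 adjusted over the list alone). The median was 4.69 (adjusted p = 1.35e-11, and adjusted p = 0.118 with an estimated correlation). RD20, a caleosin, rose by 7.35 (SE 0.18), LTI78 (RD29A) by 6.71 (SE 0.49) and COR15A by 5.90 (SE 0.21). Stress transcription factors were higher in 20 of 21 (20 adjusted over the list alone), among them NAC019, 7.04 (SE 0.22), and DREB2A, 5.93 (SE 0.24). Their median was 3.54 (adjusted p = 1.81e-10, and adjusted p = 0.118 with an estimated correlation). The clade A phosphatases, which hold back ABA signalling, were higher in 9 of 9 (9 adjusted over the list alone), with HAI1 at 8.92 (SE 0.37) and ABI1 at 3.77 (SE 0.08). The median was 4.62 (adjusted p = 1.22e-06, and adjusted p = 0.151 with an estimated correlation). ABA synthesis genes were higher in 6 of 8 and lower in 2 (6 and 2 adjusted over the list alone), and NCED3, the enzyme of the rate-limiting step, rose by 4.95 (SE 0.13). Over genes above background on all arrays alone, the ABA synthesis call was lost (mean 1.28, adjusted p = 0.191), as it was in a fit of these groups alone (0.059). Their median was 1.69 (adjusted p = 0.0344, and adjusted p = 0.151 with an estimated correlation). ABA breakdown and transport genes were higher in 8 of 10 and lower in 1 (9 and 1 adjusted over the list alone). The median was 1.77 (adjusted p = 0.0142, and adjusted p = 0.277 with an estimated correlation). PYL4, an ABA receptor, fell by 3.75 (SE 0.23).

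Jasmonate genes in WT at 2 h were higher in 23 of 25 and lower in 2 (23 and 2 adjusted over the list alone), with LOX3, a lipoxygenase, at 6.98 (SE 0.30). The median was 3.89 (adjusted p = 1.19e-11, and adjusted p = 0.118 with an estimated correlation). All 17 flavonoid and anthocyanin genes were higher (17 adjusted over the list alone), led by PAP1, a MYB activator of the pathway, at 8.63 (SE 0.26), and UF3GT, a glycosyltransferase, at 7.14 (SE 0.70, 1 of 3 arrays above background at 0 h). Their median was 2.15 (adjusted p = 4.59e-07, and adjusted p = 0.236 with an estimated correlation). Wax and cutin genes were higher in 20 of 25 and lower in 4 (20 and 4 adjusted over the list alone), with KCS2 at 6.18 (SE 0.35). The median was 1.00 (adjusted p = 0.000725, and adjusted p = 0.371 with an estimated correlation). Osmolyte genes were higher in 8 of 9 (8 adjusted over the list alone). Their median was 4.28 (adjusted p = 9.17e-05, and adjusted p = 0.118 with an estimated correlation). Senescence genes were higher in 13 of 20 and lower in 4 (13 and 4 adjusted over the list alone). The median was 1.26 (adjusted p = 0.0209, and adjusted p = 0.236 with an estimated correlation). Aquaporins were higher in 10 of 17 and lower in 3 (11 and 4 adjusted over the list alone). The median was 0.97 (adjusted p = 0.0171, and adjusted p = 0.604 with an estimated correlation). Heat shock genes were higher in 6 of 7 and lower in 1 (6 and 1 adjusted over the list alone). Their median was 3.11 (adjusted p = 0.0344, and adjusted p = 0.373 with an estimated correlation). Photosystem and Rubisco genes were lower in 23 of 32 and higher in 0 (23 and 0 adjusted over the list alone), a call lost under normexp with quantile (mean -0.29, 0.0789) and quantile normalization (-0.28, 0.123). The median was -0.34 (adjusted p = 0.00274, and adjusted p = 0.723 with an estimated correlation).

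Slide 1 held the 3 WT 0 h arrays and 1 WT 2 h array. That single array has no spread of its own and was assumed to vary like the other groups, so the test within the slide is not a replicated one for 2 h. Under that assumption 6187 genes were called within slide 1, 3288 higher and 2899 lower, and with slide as a block 6177. List means within that slide were 4.41 for ABA markers (adjusted p = 2.33e-11), 3.53 for stress factors (2.29e-10), 4.96 for phosphatases (9.55e-07), 1.85 for ABA synthesis (0.033), 1.71 for ABA breakdown (0.0234), 3.49 for jasmonate (2.13e-11), 3.42 for anthocyanin (3.2e-07), 1.42 for wax (0.00119), 3.22 for osmolytes (8.21e-05), 0.86 for senescence (0.033), 0.98 for aquaporins (0.0248), 3.04 for heat shock (0.0434) and -0.46 for photosystems (0.00269). With slide as a block the means of these lists ran the same way, and only the heat shock call was lost (3.04, adjusted p = 0.0695), while ABA receptors passed with the block (-1.42, 0.038) but not within slide 1 (-1.42, 0.0616). Lists with no call at 2 h had medians of -1.43 for ABA receptors (0.0835), 0.01 for strigolactone genes (0.778), 1.39 for low oxygen (0.114) and -0.52 for dividing cells (0.114). The antioxidant list, at -0.02 or -0.30 with genes at their bound, had a mean of the other sign.

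After 4 h in WT, 21 of 22 dehydration markers were higher (21 adjusted over the list alone), with LEA4-5 at least 311-fold and COR15A 7.14 (SE 0.21) higher. Their median was 5.08 (adjusted p = 8.31e-10, and adjusted p = 0.208 with an estimated correlation). Stress factors were higher in 18 of 21 (18 adjusted over the list alone), and phosphatases in 9 of 9 (9 adjusted over the list alone). The medians were 3.37 (adjusted p = 7.09e-08, and adjusted p = 0.208 with an estimated correlation) and 4.08 (adjusted p = 7.08e-06, and adjusted p = 0.208 with an estimated correlation). Jasmonate genes were higher in 22 of 25 and lower in 2 (the same counts adjusted over the list alone), and anthocyanin genes in 17 of 17 (17 adjusted over the list alone). The medians were 2.95 (adjusted p = 1.85e-07, and adjusted p = 0.208 with an estimated correlation) and 2.66 (adjusted p = 2.37e-06, and adjusted p = 0.317 with an estimated correlation). Wax genes were higher in 19 of 25 and lower in 3 (the same counts adjusted over the list alone), and osmolyte genes in 9 of 9 (9 adjusted over the list alone), with P5CS1, the proline synthesis enzyme, at 4.38 (SE 0.12). The medians were 1.01 (adjusted p = 0.000832, and adjusted p = 0.396 with an estimated correlation) and 1.93 (adjusted p = 0.000201, and adjusted p = 0.208 with an estimated correlation). All 32 photosystem and Rubisco genes were lower (32 adjusted over the list alone), and LHCB2.3, a light-harvesting protein, fell by 4.94 (SE 0.20). The median was -1.0 (adjusted p = 9.42e-09, and adjusted p = 0.396 with an estimated correlation). Dividing-cell markers were lower in 9 of 10 (9 adjusted over the list alone). The median was -0.86 (adjusted p = 0.0184, and adjusted p = 0.564 with an estimated correlation). The clock gene ELF4 rose by 7.87 (SE 0.43) and LHY fell by 4.44 (SE 0.25).

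With slide as a block, 7425 genes were called in WT at 4 h, and no slide held both groups. The block means were 5.17 for ABA markers (adjusted p = 3.39e-09), 3.37 for stress factors (2.05e-06), 5.30 for phosphatases (5.34e-06), 2.41 for jasmonate (3.06e-06), 3.74 for anthocyanin (8.67e-06), 1.52 for wax (0.00208), 2.64 for osmolytes (0.000285) and -1.28 for photosystems (1.1e-07). Dividing cells lost their call (-0.57, adjusted p = 0.126) and ABA receptors gained one (-1.81, 0.0194). Medians of ABA synthesis and ABA receptors at 4 h, 2.31 and -1.39, were 1.71 and -1.77 with genes at their bound, and neither list was called (0.0688 and 0.0504). Median and mean, or mean and test, differed in sign for the strigolactone, SnRK2, aquaporin, antioxidant, guard cell and flower lists. Within slide 2, 2268 genes differed between WT at 4 and 2 h, 745 higher and 1523 lower at 4 h. Between slides within a group, limma called 1 gene among WT 2 h arrays (827 at an unadjusted p under 0.05) and 26 among WT 4 h arrays (1845). Each of these sets 1 array against 2, with the single array assumed to vary like the other groups, so low counts do not exclude a slide difference.

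**Figure D3:**
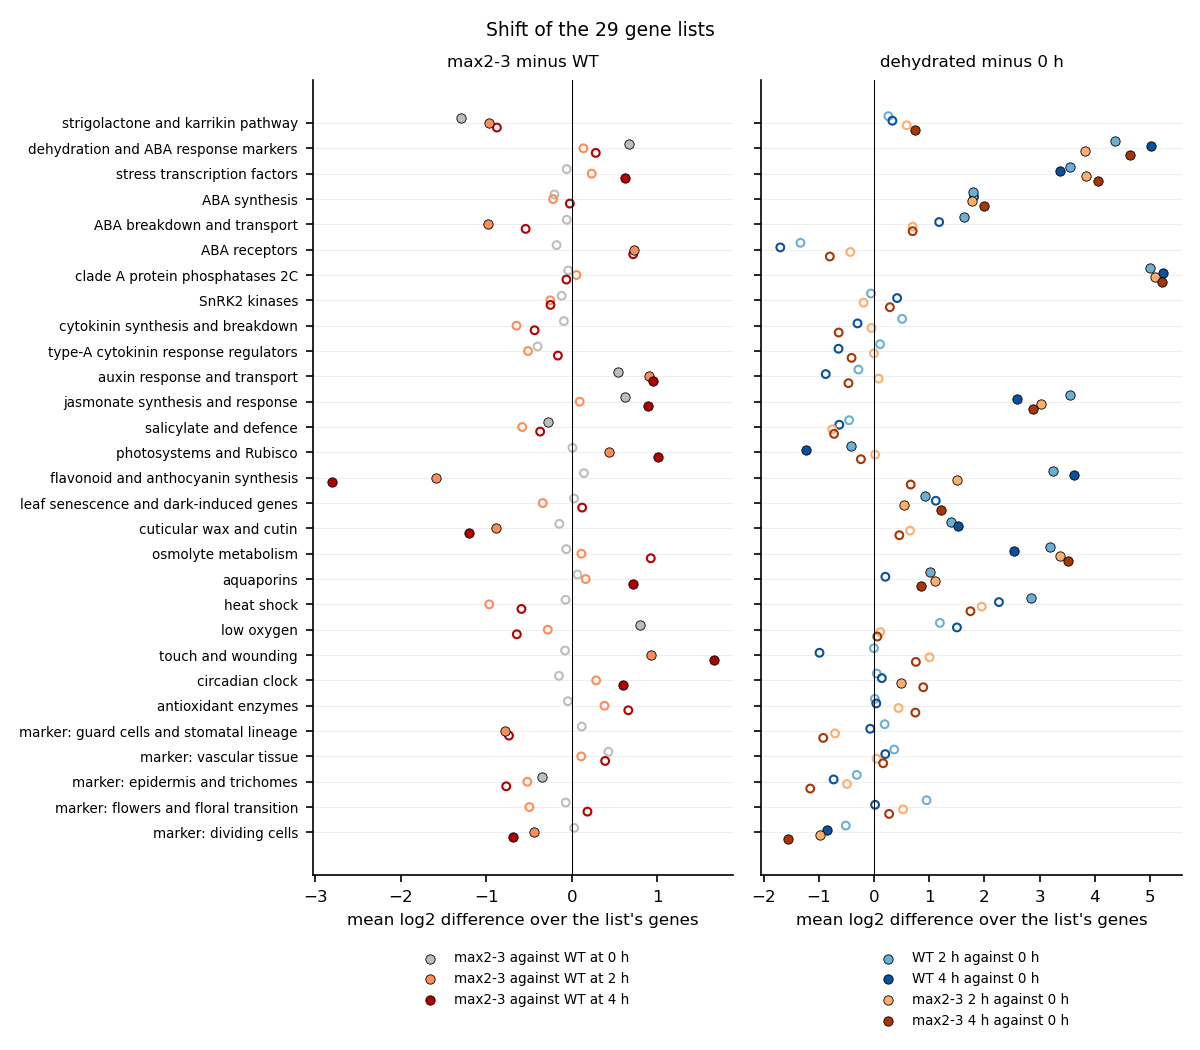
Each point is the mean log2 difference over the genes of 1 of 29 lists, between genotypes on the left and between dehydrated and 0 h leaves on the right, filled where camera called the list at the preset correlation and open where it did not. At 4 h anthocyanin genes lie at -2.81 between genotypes, and phosphatases at 5.23 in WT and 5.21 in max2-3.

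In max2-3, the same times of drying were compared with 0 h. TSPO rose by 10.49 (SE 0.33, n = 3 per group) at 2 h and by 11.11 at 4 h, MYB102, a stress transcription factor, was at least 239-fold and at least 206-fold higher, and EDL3 rose by 9.05 (SE 0.19) and 9.33. EXPA8 fell by 5.88 (SE 0.48) and then fell by 6.26, and the auxin-responsive genes AT4G34770 and SAUR26 were at least 110-fold and at least 46.6-fold lower at 4 h. Calls numbered 6309 at 2 h, 2979 higher and 3330 lower, and 8081 at 4 h, 3450 higher and 4631 lower. The max2-3 2 h and 4 h arrays each filled a slide, so slide and group cannot be told apart, and these 6 were the dimmer ones. Under median centring the balance turned at 2 h (3320 higher and 2746 lower) and the share of calls that were higher went from 42.7% to 55.1% at 4 h. It also turned at 2 h under normexp with quantile (2246 and 2134).

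At 2 h in max2-3, dehydration markers were higher in 21 of 22 (21 adjusted over the list alone), with RD20 at 7.01 (SE 0.18). Their median was 3.87 (adjusted p = 2.79e-11, and adjusted p = 0.108 with an estimated correlation). Stress factors were higher in 20 of 21 and lower in 1 (the same counts adjusted over the list alone), and phosphatases in 9 of 9 (9 adjusted over the list alone), with HAI1 at 8.56 (SE 0.37). The medians were 3.64 (adjusted p = 2.79e-11, and adjusted p = 0.101 with an estimated correlation) and 4.32 (adjusted p = 4.04e-07, and adjusted p = 0.122 with an estimated correlation). ABA synthesis genes were higher in 6 of 8 and lower in 2 (the same counts adjusted over the list alone), with NCED3 at 5.81 (SE 0.13). The median was 1.45 (adjusted p = 0.0257, and adjusted p = 0.108 with an estimated correlation), a call lost over genes above background on all arrays alone (mean 1.43, 0.114). Jasmonate genes were higher in 22 of 25 and lower in 2 (the same counts adjusted over the list alone). Their median was 3.07 (adjusted p = 2.79e-11, and adjusted p = 0.108 with an estimated correlation). Anthocyanin genes were higher in 16 of 17 and lower in 1 (the same counts adjusted over the list alone), with PAP1 at 6.0 (SE 0.26). The median was 1.1 (adjusted p = 0.000812, and adjusted p = 0.444 with an estimated correlation). Osmolyte genes were higher in 8 of 9 (9 adjusted over the list alone), and aquaporins in 11 of 17 and lower in 3 (the same counts adjusted over the list alone). The medians were 4.15 (adjusted p = 2.22e-05, and adjusted p = 0.108 with an estimated correlation) and 0.98 (adjusted p = 0.00212, and adjusted p = 0.444 with an estimated correlation). Clock genes were higher in 11 of 19 and lower in 3 (the same counts adjusted over the list alone), and dividing-cell markers lower in 9 of 10 (9 adjusted over the list alone). The medians were 0.60 (adjusted p = 0.0257, and adjusted p = 0.444 with an estimated correlation) and -0.99 (adjusted p = 0.0197, and adjusted p = 0.476 with an estimated correlation). The clock call was lost with no dim filter (0.0607). Senescence genes were higher in 10 of 20 and lower in 5 (the same counts adjusted over the list alone), a call lost without max2-3 0 h replicate 1 (mean 0.48, adjusted p = 0.0619), under median centring (0.092), with no dim filter (0.1) and with array weights (0.0577). The median was 0.69 (adjusted p = 0.041, and adjusted p = 0.306 with an estimated correlation). Photosystem genes were higher in 7 of 32 and lower in 4 (6 and 4 adjusted over the list alone). Their median was 0.05 (adjusted p = 0.293). Signs differed between median, mean and test for the cytokinin, type-A regulator and low-oxygen lists.

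At 4 h in max2-3, dehydration markers were higher in 21 of 22 (21 adjusted over the list alone), and stress factors in 20 of 21 (20 adjusted over the list alone), with DREB2A at 7.89 (SE 0.24) and ABI5 at 6.57 (SE 0.28). The medians were 4.37 (adjusted p = 2.12e-10, and adjusted p = 0.124 with an estimated correlation) and 4.21 (adjusted p = 3.01e-10, and adjusted p = 0.121 with an estimated correlation). Phosphatases were higher in 9 of 9 (9 adjusted over the list alone), and ABA synthesis genes in 6 of 8 and lower in 1 (the same counts adjusted over the list alone). The medians were 4.63 (adjusted p = 4.25e-06, and adjusted p = 0.142 with an estimated correlation) and 2.14, or 1.98 with genes at their bound (adjusted p = 0.0265, and adjusted p = 0.124 with an estimated correlation). The ABA synthesis call was lost under median centring (mean 2.24, adjusted p = 0.0516) and over genes above background on all arrays alone (1.68, 0.107). Jasmonate genes were higher in 21 of 25 and lower in 2 (the same counts adjusted over the list alone), and osmolyte genes in 9 of 9 (9 adjusted over the list alone), with BAM1 at 5.39 (SE 0.13). The medians were 2.9 (adjusted p = 1.3e-08, and adjusted p = 0.124 with an estimated correlation) and 4.23 (adjusted p = 2.67e-05, and adjusted p = 0.121 with an estimated correlation). Senescence genes were higher in 13 of 20 and lower in 2 (12 and 2 adjusted over the list alone), with NYE1 (SGR1), which dismantles chlorophyll, at 4.05 (SE 0.16). The median was 1.24, or 1.43 with genes at their bound (adjusted p = 0.00303, and adjusted p = 0.124 with an estimated correlation). Dividing-cell markers were lower in 10 of 10 (10 adjusted over the list alone), with CYCA1;1, a mitotic cyclin, at -2.69 (SE 0.17). Their median was -1.56 (adjusted p = 0.00303, and adjusted p = 0.488 with an estimated correlation). Photosystem genes were higher in 6 of 32 and lower in 12 (5 and 12 adjusted over the list alone), and anthocyanin genes higher in 7 of 17 and lower in 4 (the same counts adjusted over the list alone). The medians were -0.07 (adjusted p = 0.728) and 0.51 (adjusted p = 0.194). The low-oxygen median, -1.42, and mean, 0.06, differed in sign.

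Calls for a pair of lists in max2-3 at 4 h hung on single arrays and on the processing. Strigolactone genes were higher in 10 of 18 and lower in 3 (10 and 2 adjusted over the list alone), with HB40 at least 16.7-fold and AT4G30350 (SMXL2) 2.44 (SE 0.12) higher. The median was 0.58 (adjusted p = 0.0475, and adjusted p = 0.142 with an estimated correlation). That call was lost without max2-3 0 h replicate 1 (mean 0.68, adjusted p = 0.0629) or replicate 3 (0.76, 0.0504) and without max2-3 4 h replicate 1 (0.73, 0.0558). Aquaporins were higher in 11 of 17 and lower in 6 (the same counts adjusted over the list alone). The median was 0.93 (adjusted p = 0.0475, and adjusted p = 0.676 with an estimated correlation). Their call was lost without max2-3 0 h replicate 2 (mean 0.87, adjusted p = 0.0537) or 3 (0.82, 0.0535) and without max2-3 4 h replicate 1 (0.83, 0.0533) or 3 (0.84, 0.0523). Both also lost it under median centring (adjusted p = 0.112), with no dim filter (0.0578), with the mean of all probes (0.0505) and in a fit of these groups alone (0.0574 and 0.0514), and aquaporins under normexp with quantile (0.0633) and quantile normalization (0.065).

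Next, max2-3 was compared with WT after 2 h of drying. TT7, a flavonoid hydroxylase, was lower by -3.85 (SE 0.36, adjusted p = 5.19e-06, n = 3 per group), MYB90 (PAP2), a MYB activator of anthocyanin synthesis, at least 10.3-fold lower, and CYP707A3, an ABA hydroxylase, lower by -3.37 (SE 0.24). AT5G35935 was at least 53.2-fold and XTH33, a wall enzyme, at least 13.3-fold higher, while AT1G30250 was at least 113-fold lower, MRD1 lower by -6.43 (SE 0.24) and KCR2 by -3.76 (SE 0.14). Calls numbered 2284, 990 higher and 1294 lower in max2-3, a balance that turned under median centring (1182 and 1073).

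At 2 h, 10 lists were called. Strigolactone and karrikin genes were lower in 12 of 18 and higher in 4 (13 and 4 adjusted over the list alone), with BRC1 at least 12.5-fold lower and CCD8 (MAX4), a strigolactone synthesis enzyme, higher by 2.8 (SE 0.54). Their median was -1.03 (adjusted p = 0.00737, and adjusted p = 0.172 with an estimated correlation). Anthocyanin genes were lower in 14 of 17 (14 adjusted over the list alone), and wax genes in 19 of 25 and higher in 1 (19 and 3 adjusted over the list alone), with WSD1, a wax ester synthase, at -3.35 (SE 0.33). The medians were -1.11 (adjusted p = 9.95e-05, and adjusted p = 0.418 with an estimated correlation) and -0.54 (adjusted p = 0.000181, and adjusted p = 0.418 with an estimated correlation). Epidermis markers, whose cells make wax, had a median of -0.70 (adjusted p = 0.11). The wax mean, -0.88, was -0.57 over genes above background on all arrays alone. Guard cell and stomatal lineage markers were lower in 10 of 15 and higher in 1 (the same counts adjusted over the list alone), with SPCH, which starts the stomatal lineage, at -1.97 (SE 0.18). The median was -0.82 (adjusted p = 0.00224, and adjusted p = 0.418 with an estimated correlation). Auxin genes were higher in 12 of 15 and lower in 1 (the same counts adjusted over the list alone), with IAA5 at 2.3 (SE 0.24) and IAA1 at 2.00 (SE 0.21). Their median was 0.64 (adjusted p = 5.59e-05, and adjusted p = 0.172 with an estimated correlation). Photosystem genes were higher in 31 of 32 and lower in 1 (the same counts adjusted over the list alone), with LHCB2.3 at 1.47 (SE 0.20) and LHCB4.3 at -1.09 (SE 0.20). The median was 0.44 (adjusted p = 2.33e-09, and adjusted p = 0.418 with an estimated correlation). That call was lost under normexp with quantile (mean 0.09, adjusted p = 0.17) and quantile normalization (0.10, 0.116), and matched genes of like brightness had a median of 0.30.

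A further 4 lists were called at 2 h, each losing its call under some alternative. ABA receptors were higher in 7 of 10 and lower in 1 (the same counts adjusted over the list alone), with PYL5 at 1.29 (SE 0.20), and lost the call under median centring (adjusted p = 0.0517) and over genes above background on all arrays alone (0.0889). The median was 0.54 (adjusted p = 0.0312, and adjusted p = 0.418 with an estimated correlation). Touch genes were higher in 5 of 6 (5 adjusted over the list alone), with TCH4 at 1.68 (SE 0.27), and missed the threshold under median centring (0.0517) and quantile normalization (0.05). Their median was 0.87 (adjusted p = 0.0312, and adjusted p = 0.418 with an estimated correlation). ABA breakdown genes were lower in 5 of 10 (6 lower and 1 higher adjusted over the list alone), a call lost without WT 2 h replicate 3 (mean -1.01, adjusted p = 0.0603) or max2-3 2 h replicate 3 (-0.90, 0.0735), under quantile normalization (0.0526), over genes above background on all arrays alone (0.0942) and with array weights (0.0652). The median was -1.02 (adjusted p = 0.0415, and adjusted p = 0.418 with an estimated correlation). Dividing-cell markers were lower in 7 of 10 (7 adjusted over the list alone), a call lost without WT 2 h replicate 1 (mean -0.33, adjusted p = 0.0524) or max2-3 2 h replicate 2 (-0.36, 0.112), under normexp with quantile (-0.31, 0.0716) or quantile normalization (0.0684) and with array weights (0.103). Their median was -0.46 (adjusted p = 0.029, and adjusted p = 0.588 with an estimated correlation). The phosphatases had 0 members at either side (median 0.05, adjusted p = 0.709) and the dehydration markers 3 higher and 3 lower of 22 (2 and 3 adjusted over the list alone). The median was 0.26 (adjusted p = 0.384). The max2-3 arrays filled slide 4, apart from WT, so slide and group cannot be told apart.

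After 4 h, the comparison of max2-3 with WT gave 5263 called genes, 2512 higher and 2751 lower in max2-3, a balance that turned under median centring (3025 and 2188) and normexp with quantile (1539 and 1493). UF3GT was at least 80.2-fold lower, TT7 lower by -6.19 (SE 0.36, adjusted p = 1.17e-08, n = 3 per group) and GSTF12, a transferase needed for anthocyanin transport, by -4.84 (SE 0.40). XTH25 was at least 41.0-fold higher, CYP96A2 at least 23.5-fold, AT5G35935 at least 58.7-fold and REM22 by 5.38 (SE 0.47). KCR2 (-4.11, SE 0.14) and KUF1 (-2.27, SE 0.14) were lower, as at 0 and 2 h. The max2-3 arrays filled slide 5, so slide and group cannot be told apart here either.

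Anthocyanin genes were lower in 16 of 17 and higher in 1 at 4 h (the same counts adjusted over the list alone). The median was -2.23 and mean -2.81, or mean -2.62 with genes at their bound (adjusted p = 0.000103, and adjusted p = 0.443 with an estimated correlation). Wax genes were lower in 20 of 25 and higher in 2 (the same counts adjusted over the list alone), with CER1, an alkane-forming enzyme, at -2.24 (SE 0.20), beside an epidermis median of -1.08 (adjusted p = 0.3). Their median was -1.03 (adjusted p = 0.00178, and adjusted p = 0.443 with an estimated correlation). Photosystem genes were higher in 31 of 32 and lower in 1 (the same counts adjusted over the list alone), with LHCB2.3 at 2.9 (SE 0.20) and RCA, the activase of Rubisco, at 1.44 (SE 0.08). The 205 genes outside the lists with matched brightness had a median difference of 0.58, with quartiles of 0.161 and 0.859. The median was 0.90 (adjusted p = 1.19e-11, and adjusted p = 0.443 with an estimated correlation). The list's mean, 1.00, was 0.43 under quantile normalization and 0.44 under normexp with quantile. Jasmonate genes were higher in 19 of 25 and lower in 3 (the same counts adjusted over the list alone), with JAR1, which makes active jasmonate, at 2.31 (SE 0.18). Their median was 0.74 (adjusted p = 0.00273, and adjusted p = 0.443 with an estimated correlation). Their mean, 0.90, was 0.54 under normexp with quantile. Auxin genes were higher in 11 of 15 and lower in 3 (the same counts adjusted over the list alone), with IAA19 at 2.59 (SE 0.19). The median was 0.98 (adjusted p = 0.0126, and adjusted p = 0.443 with an estimated correlation). Touch genes were higher in 4 of 6 (4 adjusted over the list alone), with TCH3, a calmodulin-like protein, at 2.51 (SE 0.24). The median was 1.98 (adjusted p = 0.0254, and adjusted p = 0.443 with an estimated correlation).

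A further 4 lists passed at 4 h but not under every scaling. Stress factors were higher in 12 of 21 and lower in 4 (the same counts adjusted over the list alone), with CBF2 at 2.94 (SE 0.35) and DREB2A at 2.14 (SE 0.24). Their median was 0.55 (adjusted p = 0.0383, and adjusted p = 0.516 with an estimated correlation). The call was lost under normexp with quantile (mean 0.37, adjusted p = 0.147), quantile normalization (0.42, 0.177), median centring (0.0753) and a fit of these groups alone (0.0756). Aquaporins were higher in 11 of 17 and lower in 1 (the same counts adjusted over the list alone), with RD28 at 2.28 (SE 0.24), and lost the call under normexp with quantile (0.38, 0.135) and quantile normalization (0.37, 0.125). The median was 0.74 (adjusted p = 0.00234, and adjusted p = 0.443 with an estimated correlation). Clock genes were higher in 13 of 19 and lower in 4 (the same counts adjusted over the list alone), with RVE1 at 3.19 (SE 0.27) and PRR3 at -2.51 (SE 0.46), and lost it under normexp with quantile (0.37, 0.0742). Their median was 0.63 (adjusted p = 0.0192, and adjusted p = 0.443 with an estimated correlation). Dividing-cell markers were lower in 9 of 10 and higher in 1 (the same counts adjusted over the list alone), and lost the call without WT 4 h replicate 2 (mean -0.65, adjusted p = 0.0687), under normexp with quantile (-0.41, 0.147), under quantile normalization (-0.58, 0.114) and with array weights (0.0736). The median was -0.74 (adjusted p = 0.034, and adjusted p = 0.538 with an estimated correlation).

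Among lists not called at 4 h, dehydration markers stood at a median of 0.49 (adjusted p = 0.158), strigolactone genes at -0.49 (0.166), phosphatases at -0.07 (0.943), osmolytes at 1.18 (0.0657), guard cells at -0.44 (0.101) and ABA receptors at 0.49, or 0.97 with genes at their bound (0.296). CYP707A3, -4.14 (SE 0.24), and CYP707A1, -1.85 (SE 0.21), were lower while UGT71B6, which conjugates ABA, was higher by 2.07 (SE 0.20), and the ABA breakdown median, 0.16, and mean, -0.54, differed in sign. Signs also differed between median, mean or test for the ABA synthesis, phosphatase, cytokinin, type-A regulator, salicylate and senescence lists.

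The differences between the genotypes' responses were then tested. A slide difference cannot be told apart from them, as max2-3 at 2 and 4 h each filled a slide. At 2 h, 2812 genes responded differently, 1074 with a higher and 1738 with a lower change in max2-3, and at 4 h 6033, 2654 higher and 3379 lower. Median centring gave 1394 and 1396 at 2 h and turned the balance at 4 h (3391 and 2614). At 2 h KUF1, low in max2-3 from the start, differed by 2.27 (SE 0.19, adjusted p = 2.31e-05, n = 3 per group). COR15A stood at -1.81 (SE 0.30), CYP707A2 at -2.74 (SE 0.27) and LBD41 at -2.84 (SE 0.23). ELI3-2 stood at -5.77 (SE 0.93) and NATA1 at -5.20 (SE 0.85). Much of the value for ELI3-2, CYP707A2 and COR15A was their higher level in max2-3 at 0 h, not called with slide as a block. At 4 h TT7 stood at -6.35 (SE 0.51) and RLP40 at -7.38 (SE 1.09, 1 of 3 WT 0 h arrays above background). The difference was at least 42.1-fold towards max2-3 for XTH25 and at least 28.5-fold for AT3G04200, neither well above background in WT at 4 h. It was at least 6.76-fold the other way for CCD7 (MAX3), a strigolactone synthesis enzyme not well above background in WT at 0 h. UF3GT also passed (adjusted p = 9.2e-06) but, not well above background in max2-3 at 0 or 4 h, has no bound.

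At 2 h the list tests passed for photosystems (29 of 32 higher, 30 adjusted over the list alone), a call lost under normexp with quantile (mean 0.10, 0.326) or quantile normalization (0.11, 0.219). The median was 0.42 (adjusted p = 1.94e-07, and adjusted p = 0.624 with an estimated correlation), against 0.35 in genes of matched brightness. Anthocyanin genes were lower in 10 of 17 (13 adjusted over the list alone), wax genes in 15 of 25 and higher in 1 (15 and 2 adjusted over the list alone), and guard cell markers in 11 of 15 and higher in 1 (the same counts adjusted over the list alone). The medians were -1.20 (adjusted p = 0.000764, and adjusted p = 0.624 with an estimated correlation) and -0.85 (adjusted p = 0.00833, and adjusted p = 0.624 with an estimated correlation) and -0.84 (adjusted p = 0.00771, and adjusted p = 0.624 with an estimated correlation). ABA receptors were higher in 7 of 10 (8 adjusted over the list alone). Their median was 1.01 (adjusted p = 0.00665, and adjusted p = 0.521 with an estimated correlation). Clock genes were higher in 10 of 19 and lower in 1 (the same counts adjusted over the list alone), a call lost without max2-3 2 h replicate 2 (mean 0.40, adjusted p = 0.0621). The median was 0.53 (adjusted p = 0.0133, and adjusted p = 0.624 with an estimated correlation).

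The 3 weaker list calls of the 2 h difference were lost without single arrays and under other settings. Strigolactone genes were higher in 7 of 18 and lower in 1 (the same counts adjusted over the list alone). Their median was 0.45 (adjusted p = 0.0462, and adjusted p = 0.521 with an estimated correlation). The call was lost without WT 0 h replicate 2 (mean 0.29, adjusted p = 0.0596), WT 2 h replicate 1 (0.29, 0.0624) or 3 (0.34, 0.0576), max2-3 0 h replicate 1 (0.26, 0.0922) and max2-3 2 h replicate 1 (0.30, 0.0526) or 2 (0.35, 0.0621). It was also lost under normexp with quantile (0.0666), median centring (0.093), no dim filter (0.0915), the mean of all probes (0.0741), array weights (0.0831) and a fit of these groups alone (0.0574). Low-oxygen genes were lower in 2 of 9 (2 adjusted over the list alone), a call lost without WT 0 h replicate 2 (mean -1.06, adjusted p = 0.0596), WT 2 h replicate 1 (-0.99, 0.0639), max2-3 0 h replicate 2 (-0.82, 0.0994) and max2-3 2 h replicate 2 (-1.07, 0.0621) or 3 (-0.89, 0.0885), with the mean of all probes (0.0741) and in a fit of these groups alone (0.0574). The median was -0.83 (adjusted p = 0.0462, and adjusted p = 0.707 with an estimated correlation). The genotype means were 0.80 at 0 h and -0.28 at 2 h. Touch genes were higher in 4 of 6 (5 higher and 1 lower adjusted over the list alone), a call lost without WT 0 h replicate 3 (mean 0.83, adjusted p = 0.0627), WT 2 h replicate 1 (0.91, 0.0624), max2-3 0 h replicate 1 (0.98, 0.0618) and max2-3 2 h replicate 2 (1.1, 0.0598), and under median centring (0.0726). The median was 1.29 (adjusted p = 0.0451, and adjusted p = 0.624 with an estimated correlation). Signs differed for the ABA synthesis, SnRK2, salicylate and senescence lists.

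At 4 h the same tests passed for photosystems (31 of 32 higher, 31 adjusted over the list alone), anthocyanin genes (16 of 17 lower and 1 higher, the same counts adjusted over the list alone) and wax genes (16 of 25 lower and 1 higher, the same counts adjusted over the list alone). The medians were 0.87 (adjusted p = 2.24e-11, and adjusted p = 0.505 with an estimated correlation) and -2.68 (adjusted p = 0.000192, and adjusted p = 0.505 with an estimated correlation) and -1.03 (adjusted p = 0.00945, and adjusted p = 0.505 with an estimated correlation). Genes matched to photosystems on brightness had a median of 0.63 (quartiles 0.202 and 0.859). The photosystem mean, 1.00, was 0.44 under quantile normalization and 0.45 under normexp with quantile. Strigolactone genes were higher in 13 of 18 and lower in 4 (13 and 5 adjusted over the list alone), stress factors in 14 of 21 and lower in 5 (the same counts adjusted over the list alone), and both lost the call under median centring (adjusted p = 0.0563). The stress factor call was also lost under normexp with quantile (mean 0.36, adjusted p = 0.129) and quantile normalization (0.49, 0.0949). The medians were 0.90 (adjusted p = 0.0277, and adjusted p = 0.505 with an estimated correlation) and 1.01 (adjusted p = 0.0277, and adjusted p = 0.505 with an estimated correlation). Aquaporins were higher in 11 of 17 and lower in 1 (the same counts adjusted over the list alone), a call lost under normexp with quantile (mean 0.29, 0.227) or quantile normalization (0.28, 0.215). Their median was 0.69 (adjusted p = 0.00934, and adjusted p = 0.505 with an estimated correlation). Clock genes were higher in 11 of 19 and lower in 4 (the same counts adjusted over the list alone), and touch genes in 3 of 6 (5 adjusted over the list alone), the latter not without WT 4 h replicate 2 (mean 1.69, adjusted p = 0.0521). Both calls were lost under median centring (0.0522 for clock and 0.0551 for touch genes). The medians were 0.69 (adjusted p = 0.0173, and adjusted p = 0.505 with an estimated correlation) and 1.70 (adjusted p = 0.0277, and adjusted p = 0.505 with an estimated correlation). The phosphatases had a median of -0.03 (adjusted p = 0.829), or 0.23 without 2 members that have no bound. With genes at their bound, and those without one left out, the anthocyanin median was -2.61 at 4 h and -1.11 at 2 h. Signs differed for the dehydration marker, phosphatase, SnRK2, cytokinin, salicylate and vascular lists.

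**Figure D4:**
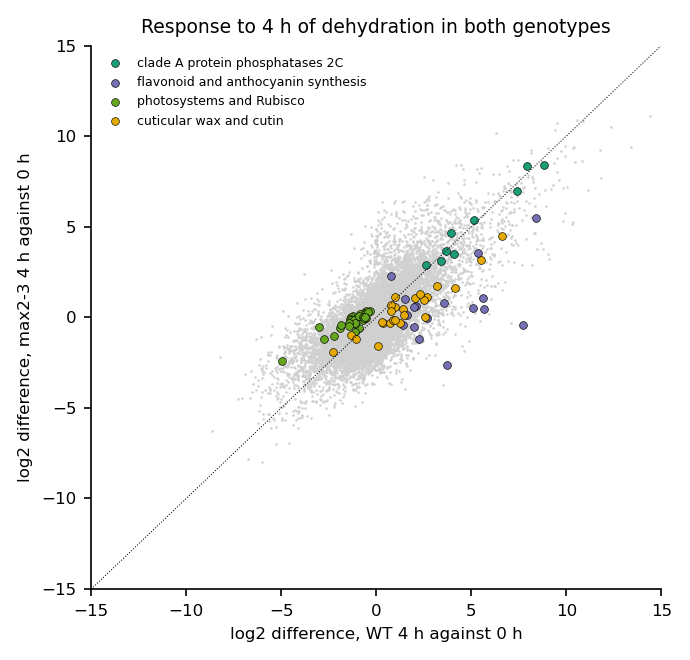
Each grey point is a gene's log2 difference at 4 h against 0 h in WT (horizontal) and in max2-3 (vertical), with members of 4 lists in colour and a dotted line where both are equal. Of 17 anthocyanin genes 16 lie below the line, with a median difference of -2.68, and phosphatases near it (-0.03).

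Across genes, the responses of the genotypes were alike in direction. The log2 changes correlated with r = 0.845 (rho 0.761) at 2 h and r = 0.739 (rho 0.661) at 4 h, values across genes, which are not independent replicates, and from comparisons that share no arrays. At 2 h 2288 genes were called higher in both genotypes, against 457 for independent lists, 1903 lower in both, against 455, and 42 in opposite directions. At 4 h these counts were 2231 against 575, 2271 against 829, and 187. Between the genotype comparisons, which share no arrays, 2 h and 4 h had 813 higher genes in common, against 119 for independent lists, and 985 lower genes, against 170. For 0 h and 4 h the common counts were 185 against 72 and 133 against 57. Opposite changes were also more common than in independent lists, with 97 genes higher at 0 h and lower at 4 h, against 78, and 78 the reverse, against 52. Between 0 h and 2 h these counts were 63 against 37 and 16 against 20. In all, 101 genes were higher and 103 lower in max2-3 at all 3 times.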

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

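The tests on the phosphatases, the spike-in test on the dimmer photosystem genes, and all counts of splits of the arrays were chosen only after the result was seen. Results stood out where the change from 0 h differed between the genotypes by its own test, for 2812 genes at 2 h and 6033 at 4 h.

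At 2 h the list means of the difference, max2-3 minus WT, were 0.33 for strigolactone genes, 0.901 for ABA receptors, 0.431 for photosystems and Rubisco, -1.735 for anthocyanin synthesis, -0.737 for wax and cutin, -1.081 for low oxygen, 1.007 for touch, 0.435 for the clock and -0.898 for guard cells. The largest positive fitted differences of single genes at 2 h were AT3G09915 (4.008), AT1G05700 (3.845), AT2G13640 (3.774), AT5G15660 (3.706), AT1G18990 (3.704) and AT2G15990 (3.672). The largest negative ones were ELI3-2 (-5.766), AT2G43870 (-5.701), AT4G13790 (-5.698), AT2G22930 (-5.474), AT2G42990 (-5.231) and NATA1 (-5.2). Of these genes only AT1G18990, ELI3-2, AT2G42990 and NATA1 were above background on at least 1 array of every group. For the others size and order are not measured: the bound was at least 9.34-fold for AT3G09915, 1.93-fold for AT2G15990, 23.2-fold for AT2G43870 and 26.7-fold for AT2G22930, and the rest have none. At 4 h the list means were 0.418 for strigolactone genes, 0.688 for stress transcription factors, 0.997 for photosystems, -2.951 for anthocyanin synthesis, -1.056 for wax and cutin, 0.653 for aquaporins, 1.744 for touch and 0.75 for the clock. The largest positive fitted differences were AT3G04200 (6.187), XTH25 (6.041), CYP96A2 (6.031), AT1G30390 (5.912), AT2G33705 (5.746) and AT2G15990 (5.639). The largest negative ones were UF3GT (-8.127), RLP40 (-7.375), AT2G43870 (-7.248), ZIP9 (-6.491), TT7 (-6.347) and AT4G11210 (-6.183). Of these only RLP40 and TT7 were above background on at least 1 array of every group. The bound was at least 28.5-fold for AT3G04200, 42.1-fold for XTH25, 18.8-fold for AT2G15990, 33.4-fold for AT2G43870 and 10.3-fold for ZIP9, and the rest, UF3GT among them, have none.

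Photosystem genes were higher in max2-3 at 4 h (median 0.902, mean 1.005, or mean 0.426 under quantile normalization). Compression of bright spots on the brighter WT slides is argued against for the 13 of 32 members no brighter than the brightest spike-in (median 1.189). The gap between that and a middle spike-in cancels a shift of both and differed by only -0.021 (SE 0.043). For the whole list compression cannot be told apart, as its median signal, 18.121, lies above the brightest spike-in, 17.886. A shift of all bright genes on the max2-3 slide may account for much of the difference: 205 genes matched on brightness had a median of 0.576. A genotype difference in the loss of these transcripts stays open, untested apart from both shifts.

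Anthocyanin genes were lower in max2-3 at 4 h (mean -2.809). A weaker response of all genes is argued against. At 4 h, of 3370 genes rising on average, 652 rose less and 820 more in max2-3. Of 3895 falling, 889 fell less and 862 more. The 9 phosphatases, picked after the result, stood at -0.021 (SE over genes 0.148), or 0.08 without 2 lacking a bound, where -4.272 was needed. Slide cannot be told apart from genotype, as slide 5 held only max2-3 at 4 h. Anthocyanin genes differed by 0.417 between WT 4 h arrays on slides 3 and 2. They differed by -0.267 between WT 2 h arrays on slides 2 and 1, each with 1 array on a side. An effect of max2-3 on this pathway under dehydration stays a hypothesis.

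Dehydration and ABA markers were higher in well-watered max2-3, with a mean of 0.668, though their difference of responses was called at neither time. A single array as the whole cause is argued against, as the lowest max2-3 array lay 0.413 above the highest WT array, but replicate 2 stood apart at 1.11, against 0.444 and 0.45, and the mean without it was 0.447. Water loss before harvest is argued against only if it moves markers and phosphatases in the proportion seen in WT at 2 h. The latter then needed 0.766 and had -0.042 (SE over genes 0.096), or 0.265 with slide as a block, 2 of 9 being below background. A difference between slides 1 and 3 stays open, though the marker mean was 0.979 with that block (adjusted p = 0.000991). Over 18 alternatives the adjusted p ran from 0.000274 to 0.0342, but with an estimated correlation it was 0.667. An effect of genotype may remain, untested.

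The 6 arrays of each comparison have 10 splits, too few for a share under 0.05, and in each only the real one gave as many genes. Over 20852 genes the real counts and the highest others were 1025 and 3 for max2-3 against WT at 0 h, 2271 and 10 at 2 h, and 5236 and 3 at 4 h. For dehydration they were 6044 and 0 in WT at 2 h, 7208 and 2 in WT at 4 h, 6277 and 1 in max2-3 at 2 h, and 8036 and 0 in max2-3 at 4 h. For the differences of responses, 11 of 100 splits of the 12 arrays gave as many genes at each time, so these counts do not exclude chance. Their highest counts, 6708 against 2799 at 2 h and 7569 against 6002 at 4 h, came from splits that mix hours of dehydration and so follow a structure of the samples. A test that splits genotypes only within each hour was chosen after those counts were seen. In it 1 of 100 splits gave as many genes at each time, with highest others of 2087 at 2 h and 5405 at 4 h. A split can leave the genotypes of 1 hour apart and carry their difference, so it bears on exchanging genotypes within an hour, and chance is not excluded for the difference of responses itself.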

How the results depend on the processing

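None of the tests in this part was chosen after the result was seen. Of 1093 calls of named genes, 876 passed the test in every alternative, and of 87 calls of lists 1 did. Over 21126 alternative values of the called genes, 713 fell short of the threshold in the same direction and 13 changed sign. Over 1783 alternative values of the called lists, 201 fell short. The direction of camera's test turned in 0 of these, but the mean of the salicylate list at 0 h, -0.276, changed sign in 3, at 0.026, 0.112 and 0.027 without WT 0 h replicate 3 and max2-3 0 h replicates 1 and 3. The estimated correlation ended 86 of the 87 list calls and fry 1, and 54 passed in every other alternative. Median centring ended 14, leaving out single arrays 14, normexp with quantile 13 and quantile normalization 12.

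With no fold minimum the counts of called genes, in the order of max2-3 against WT at 0, 2 and 4 h, WT at 2 and 4 h, max2-3 at 2 and 4 h and the differences of responses at 2 and 4 h, were 6599, 11052, 15136, 15015, 16166, 15371, 16643, 9075 and 13707, and 8859 for the overlap of 2 and 4 h (1798), by construction. Under normexp with quantile normalization max2-3 against WT gave 536, 1101 and 3032, the differences of responses 1672 and 3897, and the overlap 822, the cause not being tested. Means of called lists then fell over 1.5-fold to 0.474 for ABA receptors and -0.48 for guard cells (2 h genotype; difference -0.521), 1.746 for heat shock (WT at 2 h), and 1.067, 1.083 and 1.217 for ABA synthesis (WT at 2 h, max2-3 at 2 and 4 h). With only genes above background on all arrays, and so fewer tested, max2-3 against WT gave 628 at 0 h and 1337 at 2 h, the overlap 1051 and strigolactone differences 0.511 and 0.797. With slide as a fixed block max2-3 against WT at 0 h gave 77. As a random block (correlation -0.032) slide gave 1049, 2286, 5254, 6083, 7253, 6334, 8095, 2843 and 6059. That fit cannot remove a slide difference from max2-3 at 2 or 4 h, whose slides held no other group. The correlation of responses at 2 and 4 h was 0.864 and 0.768 under normexp with quantile, 0.804 and 0.707 with no dim filter, and 0.813 and 0.725 with array weights.

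Leaving out single arrays gave 906 to 1208, 1950 to 2796, 4993 to 5638, 5951 to 6156, 7131 to 7308, 6227 to 6371, 7967 to 8205, 2439 to 3258 and 5686 to 6375 genes, an overlap of 1545 to 2106, and correlations of 0.817 to 0.857 and 0.715 to 0.754. Replicate numbers do not pair these arrays. The replicate block gave 1015, 2269, 5257, 6071, 7246, 6301, 8081, 2763 and 6018 genes. Deviations of same-numbered arrays correlated by 0.068, 0.139 and 0.127 in WT at 2 h against 0 h, where 3 of 3 arrays correlated best with their own number, a hint from the data alone.

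Values that changed sign, for which the cause was not tested, were under normexp with quantile PIP2A at -0.135 (2 h genotype), PP2CA at -0.032 and ABI1 at -0.387 (4 h genotype), PSBO1 at -0.05 (max2-3 at 2 h), HB40, below background in max2-3 at 0 h, at a fitted -0.151 and -0.208 (differences of responses at 2 and 4 h) and CAT3 at -0.186 (difference at 4 h). Under quantile normalization PIP2A stood at -0.156, ABI1 at -0.367 and CAT3 at -0.22. WRKY54 in max2-3 at 4 h stood at 2.975 in the series table, TCH2 in WT at 4 h at -0.063 with the mean of all probes, and HAB2 at 0 h at 0.26 with slide as a block.

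Median centring moved the median of all genes by over 0.1: from -0.043 to 0.101 for max2-3 against WT at 4 h, -0.137 to -0.005 and -0.168 to 0.084 in max2-3 at 2 and 4 h, and -0.029 to 0.099 and -0.08 to 0.1 for the differences. The share of calls that were higher then went from 47.7% to 58.0%, from 47.2% to 54.7% and 42.7% to 55.1% in max2-3, from 38.2% to 50% and from 44% to 56.5%. Signal over background limits dim genes to bounds, and of 3 equal groups of genes by brightness, 40.4% of the dimmest were called at 4 h between genotypes, against 15.2% of the brightest.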

Other observations

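No test in this part was chosen after the result was seen; the genes and lists follow the same rule as the others.

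Single members of lists that were not called at 4 h passed the test between genotypes at that time. CKX5, a cytokinin oxidase, was lower in max2-3 by -2.74 (SE 0.17), RR16 (ARR16), a cytokinin response regulator, by -2.56, and ABA receptors PYL7 and PYL5 were higher by 2.38 (SE 0.22) and 2.03 (SE 0.20). Low-oxygen genes AT5G15120 (PCO1) and LBD41 were lower by -2.80 (SE 0.15) and -1.86. Stomatal lineage genes SPCH (-3.06, SE 0.18, 2 of 3 mutant arrays above background) and MUTE (at least 5.63-fold) were lower, as was GL2, a regulator of trichomes, by -2.17 (SE 0.18). The epidermis list as a whole was not called (median -1.08, adjusted p = 0.3).

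Other such members were ASN1 and CAT2. ASN1 (DIN6), an asparagine synthetase induced in the dark, was higher in max2-3 at 4 h by 3.31 (SE 0.32) and CAT2, a catalase, by 1.51 (SE 0.12), while SAG12, a protease of late senescence, was at least 4.88-fold lower. SUC2, a phloem sucrose transporter, was higher by 1.09 (SE 0.10). The lists these belong to were not called: senescence had 8 of 20 higher and 8 lower (8 and 9 adjusted over the list alone; median -0.19, adjusted p = 0.908), antioxidant enzymes a median of 0.69 (adjusted p = 0.196) and vascular markers one of 0.43 (adjusted p = 0.101). PBS3, which acts in salicylate synthesis, was lower by -3.20 (SE 0.56), and the salicylate list was not called (median 0.02, adjusted p = 0.981).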
